A study of Nannochloropsis oceanica with 8 samples.

How the data were processed

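ChIP-seq libraries of H3K9me2 and Kbu were made from *N. oceanica* IMET1 grown at 5% CO2 or switched to 0.04% CO2, with cells taken at 24 h, and single-end Illumina reads were obtained, per the labels' protocols. The labels describe 3 cultures per CO2 level and give 2 libraries per mark and level. They do not tie libraries to cultures, so p-values measure the spread between these libraries, which may be technical. The submitters' processing notes name Trim Galore, BWA, Picard, deepTools and MACS2. Versions, settings, the genome build and how peaks were called and merged are not given in the sources used here.

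Both deposited tables hold the same 6185 peaks, and 29 of their 35 columns are identical. For each library the authors deposited a pileup signal of the ChIP reads and a background signal named lambda per the file headers, the name MACS2 uses for its control background. Control libraries are not described in the labels used here. The authors also deposited a normalised value per library, a signal that equals the whole part of 10 times pileup over background, divided by 1 factor per library. This relation was checked in the values and held in 100% of peaks in each library. The factors were 1.04 and 1.19 (H3K9me2, high CO2), 0.382 and 0.425 (H3K9me2, low CO2), 3.13 and 3.2 (Kbu, high CO2) and 0.713 and 0.752 (Kbu, low CO2). Per the file headers each table adds the authors' comparison: a log2 fold change and its standard error, a test statistic given as a score (stat), a p-value, an adjusted p-value and a status. These column names are those DESeq2 writes, but the tool the authors used for this step is not given in the sources used here. The deposited fold change is high over low CO2 (correlation with the high over low means 0.9998 and 1.0), and the deposited status is an unadjusted p under 0.05 in all 6185 peaks of each table. It marks 478 H3K9me2 peaks as loss and 0 as gain, and 964 Kbu peaks as loss and 181 as gain, where loss is a lower value at high CO2. An adjusted p is given for 1029 and 2468 peaks. The lowest mean normalised value over all 8 libraries among these was 11.1 and 9.92, so peaks below that level have none.

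None of these columns is a count of reads, so no count test was run. Pileups were whole multiples of 1 step per library, which gave the reads at a peak, but reads overlapping a position are not reads per peak and the total depth of the libraries is unknown. Low was compared with high CO2 for each mark with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean trend) on log2 of the normalised value plus a pseudocount of 1, using the 4 libraries of that mark, with no filter. This is the test fixed before the data were examined for tables of normalised values. Tests were two-sided, with Benjamini-Hochberg adjustment over peaks and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates changes at low values. The prior degrees of freedom were infinite for both marks, so all peaks of a given level share 1 spread and very small p-values rest on that assumption. On simulated values with 200 of 6185 peaks changed by 1 log2 unit, 87.5% were recovered for H3K9me2 with 0 false calls, and 100% for Kbu with 1 false call. These values were drawn with residuals pooled over peaks and no control difference between CO2 levels. The simulation therefore does not measure false calls that a control difference gives. The difference between the marks in their CO2 change was tested as an interaction over all 8 libraries.

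Quantities added after the data were seen were the ratio without size factors, the ratio before rounding down, the pileup alone with libraries scaled to 1 geometric mean, and the pileup over genome background, the lowest control value of the library (shared by 36 to 145 peaks). MACS2 uses a genome-wide background as the floor of its lambda, and that the lowest value is this floor here is an assumption. To measure what the shared controls give without any effect, pileups with no CO2 change were drawn 20 times from the observed peak means and residuals and carried through the same steps. Other analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

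Alternatives fixed before the data were examined were library totals, other pseudocounts, leaving out the lowest 25% of peaks by level, a replicate block, each library left out, an adjusted p under 0.01 and a 1.5-fold minimum. Named peaks had an adjusted p under 0.05, a mean level above the lower quartile (25%) and both low-CO2 libraries on the same side of both high-CO2 libraries, and the 6 with the largest change in each direction were taken. The rule also asked for an assigned gene and allowed at most 2 unnamed items per direction. The tables carry no gene names and the reference used here lists 160 organelle genes only, so this part was dropped and peaks are given by position. For the same reason 13 gene lists fixed in advance and the position of peaks relative to genes were not analysed here. Coordinates are as the deposited tables give them. Whether starts count from 0 or 1 is not given in the sources used here.

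Replicates of a group differed by 0.501, 0.613, 1.2 and 0.846 of the squared difference that independent reads would give per peak (H3K9me2 high, H3K9me2 low, Kbu high and Kbu low CO2). Reads in a pileup at 1 position are not a full count per peak, and the log2 pileups of replicates correlated at 0.299, 0.667, 0.984 and 0.932, so each library was kept as 1 replicate. These correlations do not show that the libraries are independent. Values below 1 mean that replicates spread less than independent reads would, so p-values that rest on this spread may be too small.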

Results

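Chromatin of *Nannochloropsis oceanica* IMET1, a unicellular marine alga that stores oil, was profiled by ChIP-seq at 5% CO2 and 24 h after a switch to 0.04% CO2. One antibody was against H3K9me2, dimethylation of lysine 9 of histone H3, a mark of repressed chromatin in many eukaryotes. The other is labelled Kbu, the usual abbreviation of lysine butyrylation, a short-chain acylation of histones. The design gave 4 groups of 2 libraries, 1 group for each mark at each CO2 level, and the question was how CO2 supply alters the genomic maps of both marks. The deposited tables hold 6185 peaks on 30 chromosomes, with a median width of 1031 bp (quartiles 759 and 1169 bp). Chromosome 2 carried most of them (376) and chromosome 30 the fewest (75). The pileup at the median peak was worth 53 and 29 reads in the H3K9me2 libraries at high CO2, and 69 and 38 at low CO2. It was worth 816 and 592 reads in the Kbu libraries at high CO2, and 168 and 106 at low CO2. Counting error at the median peak was therefore 12% to 18.6% for H3K9me2 and 3.5% to 9.71% for Kbu.

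Kbu marked most of the peak set, and H3K9me2 stood little above background at most peaks. At high CO2, 5733 peaks (92.7%) had a Kbu pileup of at least 2 times the genome background in both libraries, and the median level was 3.71 ± 0.0029 (SD, n = 2). At low CO2 this held for 4653 peaks (75.2%), with a median level of 2.59 ± 0.066 (SD, n = 2). H3K9me2 reached 2 times the genome background at 10 peaks at high CO2 and 317 at low CO2, and its median level was 1.39 ± 0.069 and 1.57 ± 0.11 (SD, n = 2 each). The genome background was taken here as the lowest control value of each library. This value was 23.4 and 23.1 in the high-CO2 Kbu libraries and 9.90 to 11.7 in the others, for reasons not given in the sources used here. The comparison of Kbu levels between CO2 levels rests on it. Comparing 2 libraries with 2, an exact permutation test of such medians cannot go below p = 0.333.

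The control background at the peaks differed between the CO2 levels. Its median stood at 3.52 times its lowest value in the 4 low-CO2 columns and at 1.28 times in the 4 high-CO2 columns. Against this control, the median Kbu ratio was 2.84 ± 0.1 at high CO2 and 0.733 ± 0.021 at low CO2 (SD, n = 2 each). The H3K9me2 ratio was 1.11 ± 0.093 and 0.453 ± 0.029 (SD, n = 2 each). At least 2-fold enrichment over the control in both libraries was found for Kbu at 5206 peaks at high CO2 and 15 at low CO2, and for H3K9me2 at 9 and 17 peaks. The deposited values divide out this overall shift with 1 size factor per library, so the changes below are relative to the bulk of the peaks. Without size factors the median change from high to low CO2 was -1.28 on the log2 scale for H3K9me2 and -1.96 for Kbu. On the pileup over genome background it was 0.18 and -0.53.

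**Figure D1:**
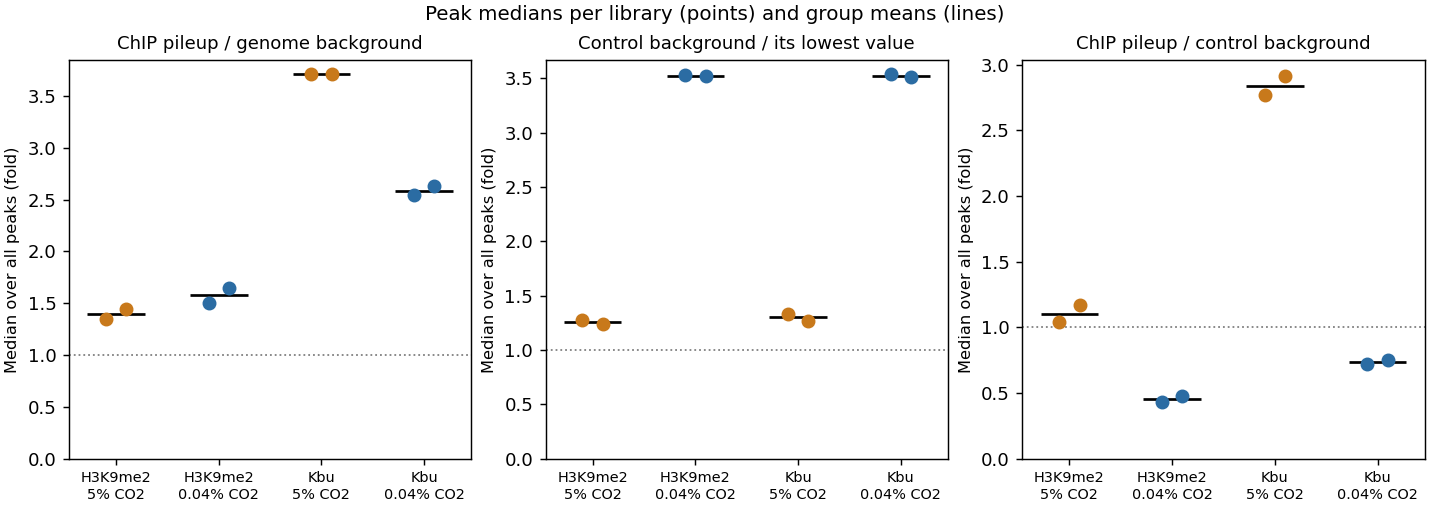
Median over all 6185 peaks (y axes, fold) of the ChIP pileup over genome background, of the control background over its lowest value, and of the ChIP pileup over the control, for each library (points) and as group means (lines). The control stands at about 3.5 in each low-CO2 column, and the Kbu ratio lies below 1 at low CO2 although its pileup lies above 2.

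The normalised H3K9me2 ratio to control differed between CO2 levels at 2266 of the 6185 peaks, relative to the bulk of the peaks. It rose at low CO2 at 1516 peaks and fell at 750, while 3919 did not pass (limma, Benjamini-Hochberg adjusted p under 0.05, n = 2 per group). The control differed too, and pileups drawn with no CO2 change gave 2417 to 2570 such calls, so these counts are not counts of changed H3K9me2. The pileup with no control passed at 312 peaks. The 6 named peaks with the largest gains lay on chromosomes 16, 20, 1, 6, 1 and 21. Peak peak1824 (chromosome 16, 696238 to 696947) went from a normalised ratio of 9.35 ± 1.0 to 95.5 ± 2.0 (SD, n = 2 each), a log2 change of 3.22 (SE 0.18). Peak peak2876 (chromosome 20, 613745 to 614534) rose from 11.3 ± 1.7 to 93.9 ± 6.9, a log2 change of 2.96 (SE 0.19, limma adjusted p = 9.4e-53).

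The 4 other named gains were peak165 (chromosome 1, 803003 to 803902, log2 change 2.82), peak5246 (chromosome 6, 691142 to 692271, 2.78), peak102 (chromosome 1, 521618 to 522158, 2.73) and peak2967 (chromosome 21, 295365 to 296006, 2.71). All 6 also rose on the H3K9me2 pileup with no control, by 0.72 to 1.44 on the log2 scale. Their control background was lower at low CO2, by -2.04 to -1.34 relative to the bulk of the peaks. At peak2876 the pileup went from 1.74 ± 0.13 to 5.44 ± 0.76 times the genome background (SD, n = 2 each).

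The named losses were smaller, with log2 changes from -1.23 to -0.93 and a largest adjusted p of 1.6e-05 (limma, n = 2 per group). They were peak261 (chromosome 1, 1227377 to 1228498), peak2588 (chromosome 2, 938109 to 939336), peak3266 (chromosome 23, 313960 to 315208), peak3167 (chromosome 22, 454894 to 456130), peak763 (chromosome 11, 865064 to 866152) and peak5260 (chromosome 6, 746836 to 747733). The ratio at peak261 went from 13.0 ± 0.56 to 4.97 ± 0.38 (SD, n = 2 each). Before rounding down, its pileup over control went from 1.54 ± 0.076 to 0.279 ± 0.0029, and its log2 change was -1.24. At the 6 named losses pileup over control was 0.268 to 0.324 at low CO2, where rounding leaves few whole steps. At low CO2 peak2588 therefore has the same value of 4.97 ± 0.38, and this SD reflects the library factors rather than replicate spread. On the pileup alone peak2588 and peak5260 fell (adjusted p = 0.0088 and 0.015, limma). The other 4 did not pass there, with peak261 at -0.45 (adjusted p = 0.064) and peak3167 at -0.28 (adjusted p = 0.41). On the pileup over genome background none of the 6 passed. In ratio peak3266, peak3167, peak763 and peak5260 no longer passed without high-CO2 replicate 2 (adjusted p = 0.12, 0.063, 0.12 and 0.063), nor peak5260 without high-CO2 replicate 1 (0.058). Peaks that rose in ratio were narrower (median 707 bp) than those that fell (1167 bp) or did not pass (1058 bp). On the pileup alone this order was turned, with a median of 1166 bp at higher and 842 bp at lower peaks. Where the ratio rose, the low-CO2 control stood at a median of 2.22 times its lowest value, against 5.17 at peaks that fell.

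Over all peaks, the change of the H3K9me2 ratio correlated at -0.886 with the change of the control and at 0.323 with the change of the pileup. These correlations are across peaks, which are not independent replicates. On the pileup alone 248 peaks were higher and 64 lower at low CO2, and 146 peaks (125 higher, 21 lower) passed the same way on ratio and pileup, while 19 passed in opposite directions. Over genome background 304 peaks were higher and 0 lower in limma (21 lower at an unadjusted p under 0.05). Among peaks called both ways, chosen after their values were seen, peak2482 (chromosome 2, 516167 to 517825) rose by 1.23 in ratio and 1.44 in pileup, and peak2708 (chromosome 2, 1456314 to 1457367) by 1.65 and 1.39. In the authors' deposited table, 296 of the 1029 H3K9me2 peaks with an adjusted p had one under 0.05, all of them lower at high CO2 than at low CO2. No peak with a mean value under 11.1 has an adjusted p there, and 67 of the 296 passed the same way on the pileup alone. Scaled to library totals, the split was 879 higher and 1779 lower. The ratio counts were 832 higher and 59 lower without high-CO2 replicate 1, and 846 and 78 without high-CO2 replicate 2. Leaving out any 1 library gave, on the pileup alone, 142 to 159 gains, and losses were 7 without high-CO2 replicate 2 and 16 without low-CO2 replicate 2. The labels give each H3K9me2 library its own antibody lot, with consecutive numbers, and whether these are true lots is not given in the sources used here.

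The normalised Kbu ratio to control differed between CO2 levels at 4354 of the 6185 peaks, relative to the bulk of the peaks. It rose at low CO2 at 2474 peaks and fell at 1880, and 1831 did not pass (limma, adjusted p under 0.05, n = 2 per group). Draws with no CO2 change gave 3815 to 3970 such calls from the control alone, and over genome background the split was 222 higher and 5174 lower. The 6 named gains were at peaks where Kbu lay near or below the genome background at high CO2 (0.736 to 1.14 times). At peak5611 (chromosome 7, 1037585 to 1038659) the pileup went from 0.871 ± 0.061 to 3.63 ± 0.04 times the genome background (SD, n = 2 each), and the ratio rose by 3.97 on the log2 scale (SE 0.09). At peak3461 (chromosome 24, 592642 to 595569) the pileup went from 0.984 ± 0.061 to 5.15 ± 0.049, and the ratio rose by 3.80 (SE 0.10).

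The other named Kbu gains were peak748 (chromosome 11, 804022 to 804719, log2 change 3.68), peak4257 (chromosome 3, 1030681 to 1031720, 3.67), peak1583 (chromosome 15, 498310 to 498979, 3.55) and peak1824 (3.37), which was also the largest H3K9me2 gain. All 6 rose on the pileup alone, by 1.52 to 2.89. Their control background was lower at low CO2, by -2.04 to -1.14 relative to the bulk of the peaks. All 6 rose over genome background too, with adjusted p between 3.3e-06 and 4.6e-05 (limma, n = 2 per group).

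The named Kbu losses were at wide peaks (1557 to 2454 bp) with strong Kbu at high CO2. At peak5367 (chromosome 6, 1281463 to 1283917) the pileup went from 9.69 ± 0.028 to 2.4 ± 0.014 times the genome background (SD, n = 2 each) and the ratio fell by 3.13 (SE 0.13, limma adjusted p = 6.1e-124). At peak3847 (chromosome 28, 81058 to 82866) the pileup went from 7.4 ± 0.00087 to 1.77 ± 0.014 and the ratio fell by 2.21. The others were peak3653 (chromosome 26, 243431 to 245447, -2.17), peak3755 (chromosome 27, 151359 to 153694, -1.77), peak5211 (chromosome 6, 557247 to 558804, -1.62) and peak1640 (chromosome 15, 746767 to 748368, -1.58). All 6 fell on the pileup alone, by 0.39 at peak5211 and 1.56 at peak3847, and all 6 also fell over genome background. Their control background was higher at low CO2, by 0.62 to 1.70 relative to the bulk of the peaks. There the low-CO2 control stood at 6.04 to 12.9 times its lowest value, above the low-CO2 Kbu pileup (1.77 to 3.58 times). At peak5367 (12.9), peak3653 (11.2), peak3755 (9.01) and peak5211 (10.4) the control was also above the high-CO2 Kbu pileup, but not at peak3847 and peak1640. The low-CO2 pileup over control was 0.185 to 0.394 at these peaks, where rounding down leaves few whole steps. Outside the named set, peak2729 (chromosome 2, 1549565 to 1551183), chosen after its values were seen, had the largest pileup loss among peaks called both ways (-1.63), from 5.11 ± 0.035 to 1.16 ± 0.041 times the genome background.

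Peaks whose Kbu ratio rose were again narrower (median 812 bp) than those that fell (1150 bp), and on the pileup alone the medians were 960 and 1074 bp. Where the Kbu ratio rose, the low-CO2 control stood at a median of 2.56 times its lowest value, against 4.74 at peaks that fell.

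On the pileup alone 1347 Kbu peaks were higher and 1556 lower at low CO2, and 2052 peaks (1059 higher, 993 lower) passed the same way on ratio and pileup, with 193 in opposite directions. These pileup calls are relative to the bulk of the peaks. The median level of the higher peaks was 3.02 times the genome background at high CO2 and 2.84 at low CO2. That of the lower peaks was 4.27 and 2.3. The change of the Kbu ratio correlated across peaks at -0.851 with the change of the control and at 0.725 with the change of the pileup. In the authors' deposited table, 624 of the 2468 Kbu peaks with an adjusted p had one under 0.05, 623 of them lower at high CO2 and 1 higher. No peak with a mean value under 9.92 has an adjusted p there, so this split leaves out peaks of low value. By the unadjusted p over all peaks it was 964 lower and 181 higher at high CO2. On the pileup alone 454 of the 624 passed the same way. Scaled to library totals, the Kbu split was 1936 higher and 2507 lower, and before rounding down it was 1967 and 2524. Losses thus outnumbered gains in both, unlike in the main test. The ratio counts were 1528 higher and 966 lower without high-CO2 replicate 1, and the count of losses was 866 without high-CO2 replicate 2. The pileup-alone counts were 803 and 826 without high-CO2 replicate 1, and 806 and 840 without replicate 2.

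**Figure D2:**
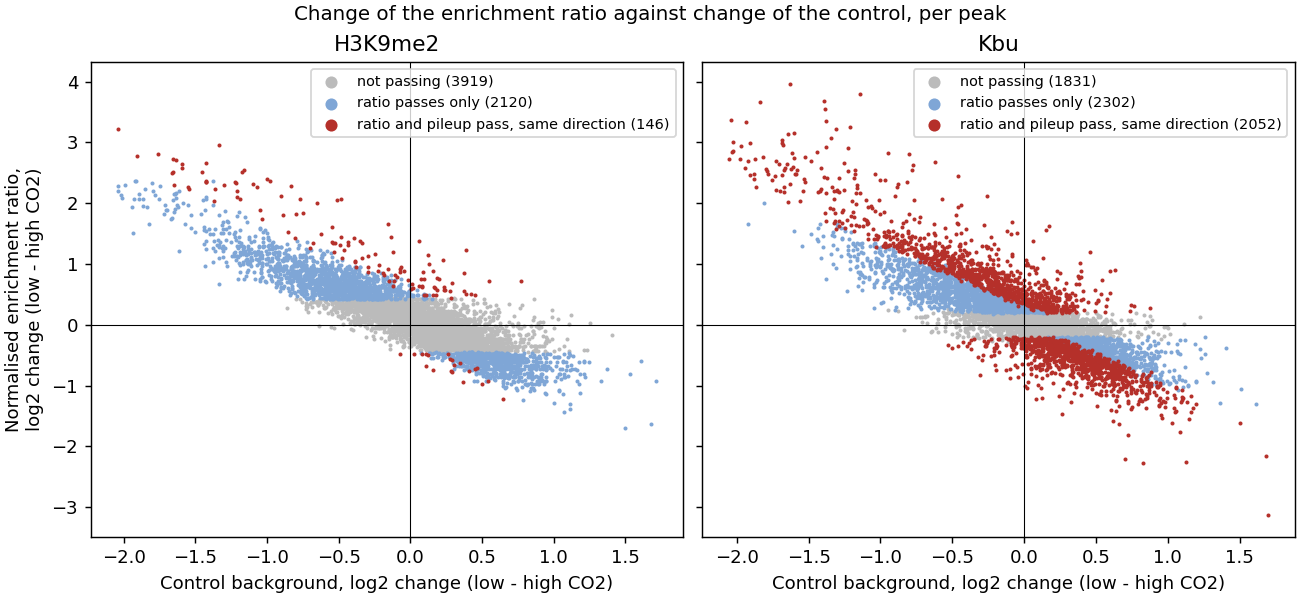
Log2 change of the normalised enrichment ratio (y axis) against log2 change of the control background (x axis), both low minus high CO2 and relative to the bulk of the peaks, for each of 6185 peaks of H3K9me2 (left) and Kbu (right). Red points passed the same way on ratio and pileup (146 and 2052 peaks), blue points passed on the ratio without a pileup call in the same direction, and the ratio falls as the control rises in both panels.

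Control background entered both of these comparisons. When pileups were drawn 20 times with no CO2 change and divided by the observed controls, the same limma test called 2417 to 2570 H3K9me2 peaks (2266 observed) and 3815 to 3970 Kbu peaks (4354 observed). The same draws gave 0 calls on the pileup alone. The log2 control values correlated across peaks at 0.9987 to 1.0 among the low-CO2 columns and at 0.963 to 0.989 among the high-CO2 columns, but at 0.440 to 0.449 between CO2 levels. Replicates of a group therefore share a control profile, and a difference between controls is not part of the replicate spread on which the p-values rest.

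The marks shared many calls. On the ratio, 1378 peaks rose in both marks and 672 fell in both, while 20 rose in H3K9me2 and fell in Kbu and 1 did the reverse. Independent lists of the same sizes would share 606 and 228 peaks. Without H3K9me2 high-CO2 replicate 1 or 2 the joint gains were 803 and 816 and the joint losses 57 and 78, and joint losses were 446 without Kbu high-CO2 replicate 2. The draws with no CO2 change, which hold the control common to both marks, shared 1242 to 1299 and 980 to 1086. The log2 changes of the marks correlated at 0.849, against 0.921 to 0.926 in the draws, and their covariance was 0.309, against 0.241 to 0.245. Joint gains and covariance thus lay above all 20 draws, and joint losses and correlation below all 20, while the draws alone gave most of the overlap.

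Joint gains also stood out on the pileup alone, which holds no control. There 173 peaks rose in both marks relative to the bulk of the peaks, against 54.0 for independent lists (odds ratio 9.36, Fisher's exact test, two-sided, p = 1.6e-61, adjusted over 4 tests p = 6.4e-61). With any 1 library left out, joint gains were 110 to 188, and more than independent lists give each time. Joint losses numbered 24 against 16.1 (Fisher's exact test, p = 0.029, adjusted p = 0.029), but this did not hold up. They were 1 without H3K9me2 high-CO2 replicate 2 (Fisher's exact test, p = 0.69), 4 without low-CO2 replicate 2 (p = 1) and 16 without low-CO2 replicate 1 (p = 0.12), and 11 and 13 without Kbu high-CO2 replicates 1 and 2 (p = 0.36 and 0.14). Peaks that rose in H3K9me2 and fell in Kbu were fewer than independent lists give, 13 against 62.4 (adjusted p = 1e-16), and this held without any 1 library. The reverse was seen at 6 against 13.9 (adjusted p = 0.019), and did not pass without H3K9me2 high-CO2 replicate 2 (0 peaks, Fisher's exact test, p = 0.36), low-CO2 replicates 1 or 2 (p = 0.37 and 0.55) or Kbu high-CO2 replicate 2 (p = 0.059). Fisher's test treats peaks as independent, which neighbouring peaks are not. Over genome background, which is not relative to the bulk, 93 peaks rose in both marks, against 10.9 for independent lists. On that scale 128 peaks rose in H3K9me2 and fell in Kbu, more than the joint gains but fewer than independent lists give (254). The changes of the marks correlated at 0.362 across peaks on the pileup alone. The log2 H3K9me2 pileup at low CO2 correlated at 0.364 to 0.424 with the Kbu pileup at low CO2. With the Kbu pileup at high CO2 it correlated at 0.115 to 0.133. Whether material shared between the low-CO2 libraries of both marks gives joint gains was not tested.

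H3K9me2 and Kbu were also followed at the 10 peaks with H3K9me2 of at least 2 times the genome background in both high-CO2 libraries, a set chosen after the values were seen. They lay on chromosomes 11 (peak748 and peak749), 15 (peak1583 and peak1602), 19 (peak2254), 3 (peak4256 and peak4257), 7 (peak5543 and peak5611) and 9 (peak6010). Their H3K9me2 pileup was 2.5 to 4.36 times the genome background at high CO2 and 2.38 to 7.85 at low CO2, and 7 of the 10 rose on the pileup alone (limma, n = 2 per group). The largest level was at peak749 (chromosome 11, 805408 to 806535), which went from 3.84 ± 0.43 to 7.85 ± 0.11 (SD, n = 2 each). The exceptions were peak4257 (adjusted p = 0.73), peak5543 (0.42) and peak6010 (0.6). These H3K9me2 calls hang on single libraries, with 4 and 0 of the 10 passing without high-CO2 replicates 1 and 2, and 5 and 3 without low-CO2 replicates 1 and 2.

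Kbu rose at all 10 of these peaks on the pileup alone (9 without Kbu high-CO2 replicate 1, where peak6010 did not pass, or replicate 2, where peak5543 did not), and at 6 of them over genome background. At peak748, peak1583, peak1602, peak4257 and peak5611 it went from 0.736 to 1.14 times the genome background at high CO2 to 2.97 to 3.63 at low CO2. At peak1602 (chromosome 15, 586050 to 586585) it went from 0.991 ± 0.071 to 2.97 ± 0.016 (SD, n = 2 each). The sixth was peak749, from 2.35 ± 0.017 to 4.5 ± 0.63. The remaining 4 peaks already carried Kbu of 4.18 to 5.56 times the genome background at high CO2. Over genome background peak2254 (-0.05, adjusted p = 0.47) and peak4256 (-0.17, adjusted p = 0.057) did not pass, and peak5543 and peak6010 fell (adjusted p = 0.018 and 0.02, limma), so the direction at these 4 turns with the scaling.

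**Figure D3:**
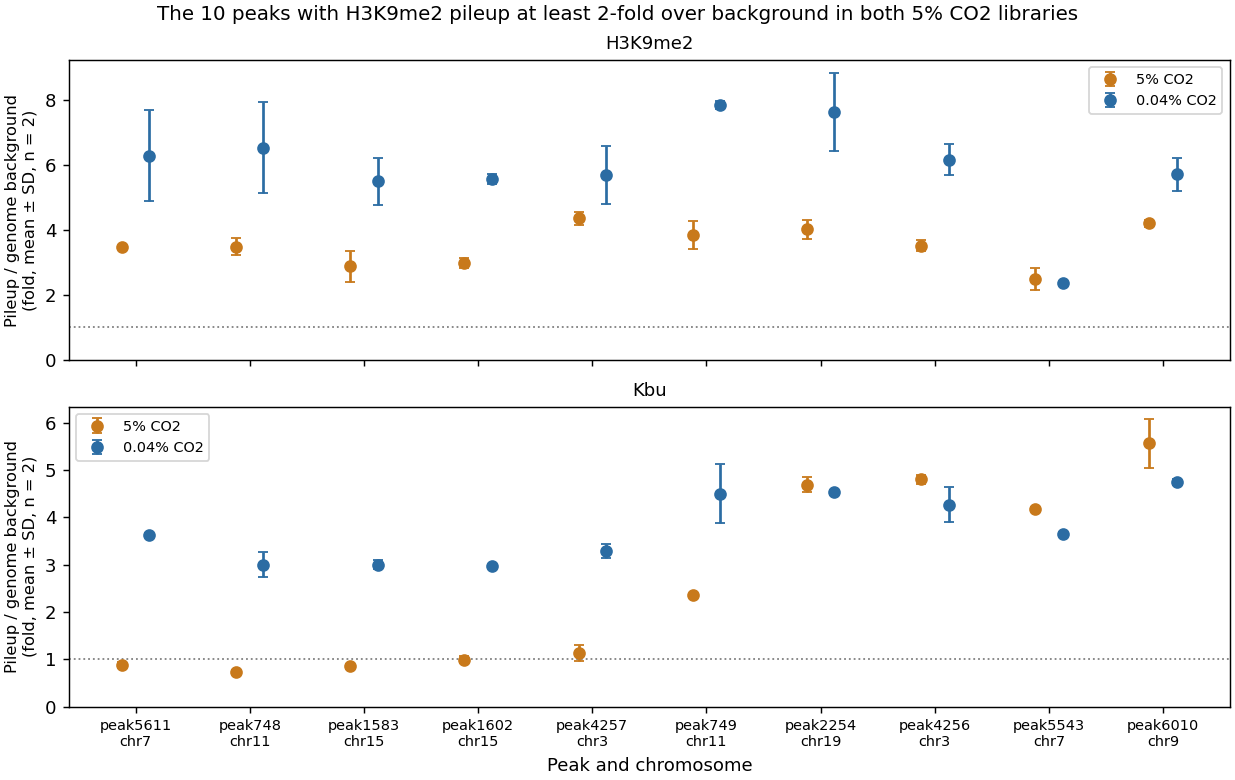
Pileup over genome background (y axes, fold, mean ± SD of 2 libraries) of H3K9me2 (top) and Kbu (bottom) at 5% and 0.04% CO2, at the 10 peaks (x axis) with H3K9me2 of at least 2 times the genome background in both 5% CO2 libraries. Kbu stands between 0.736 and 1.14 at high CO2 and between 2.97 and 3.63 at low CO2 at the 5 peaks on the left.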

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

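The CO2 change differed between H3K9me2 and Kbu, by the interaction test of limma, at 419 peaks on the ratio, with the H3K9me2 change above the Kbu change at 208 and below it at 211. On the pileup alone this held at 731 peaks, above at 385 and below at 346. The balance depends on the scaling, with 136 above and 405 below under library totals, 4839 and 28 over genome background and 4367 and 28 without size factors. Leaving out 1 library at a time gave 123 to 808 peaks on the ratio and 277 to 864 on the pileup alone, both lowest without Kbu high-CO2 replicate 1. Neither this test nor any of its runs was fixed before the files were read. The test pools 1 spread over both marks, although on the ratio the SD was 0.189 for H3K9me2 and 0.102 for Kbu. The pooled SD was 0.119 without H3K9me2 low-CO2 replicate 1 and 0.166 without Kbu high-CO2 replicate 1. The range of counts may thus partly follow which library is left out of the pooled spread.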

How the results depend on the processing

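The counts depended on the quantity tested, and the pileup and scaling quantities other than library totals were chosen after the data were seen, as was every setting for joint calls except an adjusted p under 0.01, and the interaction. The cause was not tested except where named. H3K9me2 gains and losses (1516 and 750) were 879 and 1779 with library totals, 248 and 64 on the pileup alone, 304 and 0 over genome background, and 85 and 5758 without size factors, which keep the overall shift. Losses were 1522 before rounding down, 201 without the lowest 25% of peaks, which held 531 of the 750, 453 at an adjusted p under 0.01 and 445 at 1.5-fold. Kbu gains and losses (2474 and 1880) were 222 and 5174 over genome background and 101 and 6045 without size factors, gains were 1347 on the pileup alone, and at 1.5-fold they were 1242 and 636. Joint gains (1378) were 806 with library totals, 173 on the pileup alone, 93 over genome background and 72 without size factors. Joint losses (672) were 1522, 24, 0 and 5755 in that order, 1362 before rounding down and 403 at an adjusted p under 0.01. The interaction (419 peaks) gave 731 on the pileup alone, 642 before rounding down, 4867 over genome background and 4395 without size factors.

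The median log2 change of H3K9me2 (0.08) was -0.16 with library totals, -1.28 without size factors, -0.057 before rounding down, -0.02 on the pileup alone, 0.18 over genome background and 0.40 over peaks above the median level. That of Kbu (0.07) was -0.073, -1.96, -0.074, -0.027, -0.53 and 0.13. In the authors' deposited table the H3K9me2 count (296) was 478 at an unadjusted p under 0.05 and 158 at an adjusted p under 0.01, and the Kbu count (624) was 1145 and 408.

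Leaving out 1 library at a time gave 832 to 1277 H3K9me2 gains, 59 to 645 losses, 1528 to 2589 Kbu gains and 866 to 2001 losses, where a lone library is assumed to vary like the pair. It gave 803 to 1381 joint gains, 57 to 677 joint losses and 123 to 808 interaction peaks. H3K9me2 counts were lowest without high-CO2 replicate 1 (832 and 59) or 2 (846 and 78), and Kbu counts without high-CO2 replicate 1 (1528 and 966) or 2 (866 losses). On the pileup alone H3K9me2 gains were 159, 143, 142 and 150 and losses 67, 7, 45 and 16 without high-CO2 replicates 1 and 2 and low-CO2 replicates 1 and 2. Kbu gains were 803 and 806 and losses 826 and 840 without high-CO2 replicates 1 and 2. Of the 24 named changes, 4 no longer passed on the pileup alone and 6 over genome background, all H3K9me2 losses. Naming required both low-CO2 libraries on the same side of both high-CO2 libraries. Runs without 1 library, with other pseudocounts, with a replicate block or without the lowest peaks therefore could not reverse a sign. Only runs that changed the scaling or the quantity tested could, and none of the 24 reversed in those. Without H3K9me2 high-CO2 replicate 1 or 2, 1 and 4 of the 12 named H3K9me2 changes, all losses, did not pass.

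Deviations of same-numbered libraries of a mark correlated at 0.039 and 0.12, with 2 pairs per mark, too few to show that pairing is absent. Control columns of the 2 marks correlated at 1.0 and 0.9998 for the same number at low CO2, and at 0.999 and 0.9987 across numbers. At high CO2 these were 0.9888 and 0.9796, and 0.9794 and 0.9633. Same-numbered libraries of both marks may thus share a control, which the interaction test does not model. A replicate block gave 1665 gains and 821 losses for H3K9me2 and 2456 and 1881 for Kbu. With no read counts or gene names, edgeR and DESeq2 count tests, TMM and RLE scaling, filterByExpr, gene lists, position relative to genes and an overlap joined by genes were not run. Both tables share 1 peak set, so covering at least 50% of the shorter peak changes nothing. Reads at the median peak (29 to 69) limit H3K9me2 more than Kbu (106 to 816).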

Other observations

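The tests in this part were chosen after the patterns had been seen. Changes on the pileup alone were not spread evenly along the genome. H3K9me2 gains made up 11.5% of the 122 peaks of chromosome 26, against 4.01% of all peaks (Fisher's exact test, two-sided, adjusted p = 0.014). Kbu losses were more frequent on chromosome 6 (34.9%) and less frequent on chromosomes 2 (17.6%) and 3 (18.0%) than over all peaks (25.2%), with adjusted p of 0.014, 0.014 and 0.047. These were the 4 of 120 tests over chromosomes, marks and directions that passed on the pileup, and 0 of 120 passed on the ratio (3 at an unadjusted p under 0.05). With 1 library left out, chromosome 26 was at an unadjusted p of 0.0027 to 0.21, above 0.05 without H3K9me2 high-CO2 replicate 2 or low-CO2 replicate 1, and chromosome 3 was at 0.13 without Kbu low-CO2 replicate 2. Neighbouring peaks both gained H3K9me2 in 20 pairs, against a mean of 10.2 in 10000 permutations (adjusted p = 0.02), and both lost Kbu in 447 pairs, against 398 (adjusted p = 0.02). Gains of Kbu and losses of H3K9me2 did not pass this test (adjusted p = 0.24 each), and no class of ratio calls did (smallest adjusted p = 0.24).

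H3K9me2 may rise more near chromosome starts. The 52 peaks that began within 10 kb of coordinate 1, on 27 chromosomes, had a median log2 pileup change of 0.14, against -0.02 at the others, and 10 of them were called higher. The median was above 100% of those from 10000 rotations of the changes along each chromosome. Chromosome ends were not analysed here because the lengths were not in the tables used, and repeats that affect mapping near starts were not tested.

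The gain of Kbu at the 10 peaks rich in H3K9me2 at high CO2 was set against other peaks of similar high-CO2 Kbu level. A low Kbu level alone may not account for it, but a tie to H3K9me2 level is not shown within the set. Over these 10 peaks, the median log2 change of Kbu over genome background was 1.23. In 10000 sets of other peaks matched on high-CO2 Kbu level (median 1.63 times background in both), the median of the medians was 0.10 and the highest 0.87, so the rich peaks exceeded 100% of the sets. All 10 lay above the median change of their own up to 50 nearest peaks by Kbu level, though over genome background the values of 4 of them were below 0 (peak2254, peak4256, peak5543 and peak6010). At these 4, H3K9me2 at high CO2 was 2.5 to 4.21 times background and Kbu 4.18 to 5.56 times. At peak748, peak1583, peak1602, peak4257 and peak5611, which rose by 1.53 to 2.06, they were 2.88 to 4.36 and 0.736 to 1.14 times. Within the set the gain thus went with low Kbu at high CO2, not with more H3K9me2. Members such as peak748 and peak749 are neighbours, so the 10 are not independent. The set holds 6 of the 222 peaks that rose over genome background, and strong gains outside it, such as peak3461 (0.984 to 5.15 times), also began at low Kbu, so this does not speak for Kbu gains in general. Whether repeated sequence at these peaks raises both pileups was not tested without a genome. Nor was it tested whether H3K9me2 material in the low-CO2 Kbu libraries raises Kbu there.

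The low-CO2 control background, which enters the ratio as its divisor, stood at 3.52 times its lowest value at the median peak, against 1.28 at high CO2. A bias of fragmentation or mapping in all low-CO2 libraries would in the simplest case give the H3K9me2 low-CO2 pileup the same profile, with a slope near 1 on the log2 scale. The slope was 0.145 (95% interval 0.131 to 0.159, resampling chromosomes), but it was below 1 at high CO2 too (0.324) and was 0.55 for the low-CO2 Kbu pileup, so what slope such a bias would leave is unknown and it stays open. A full exchange of a flat control with the low-CO2 Kbu libraries would leave these near background at the peaks, but they stood at 2.59 times the genome background. This does not cover a mixture or another mislabelling, which stay open. Across peaks, the low-CO2 control followed the high-CO2 Kbu pileup at Spearman 0.796 to 0.804. The low-CO2 Kbu pileup followed it less closely (0.666 to 0.677). ChIP-like material in the low-CO2 control may account for the high control values. That control followed the high-CO2 Kbu pileup more closely than the high-CO2 control did, by 0.389 in Spearman correlation. A biological change in open chromatin seen by the control stays open and was not tested.

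The difference between the controls is a candidate explanation for most ratio calls. With no CO2 change in the pileups, it gave 111% as many H3K9me2 calls as observed and 89.5% as many Kbu calls, and an average draw called 70.2% and 70.7% of the observed calls in the same direction. Calls on the ratio that passed the same way on the pileup made up 6.44% of the H3K9me2 calls and 47.1% of the Kbu calls, where independent lists would give 3.03% and 23.2%, but the ratio contains the pileup, so this excess does not separate the explanations. At 37 of these 146 H3K9me2 peaks and 845 of these 2052 Kbu peaks the control moved by more than the pileup, in either direction. The pileup changes themselves, which hold no control, remain open to an effect of CO2 or to other differences between libraries, which were not tested.

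Kbu pileup over genome background was lower at low CO2 at most peaks, from a median of 3.71 to 2.59. A single dilution of the Kbu signal by background could not raise a peak past background, yet 3.59% of peaks (222) were higher, 221 of them with a low-CO2 level above background. If the assumed background is right, dilution does not account for those. The count rests on that background, which was 23.4 and 23.1 in the high-CO2 Kbu libraries and 11.6 and 11.3 in the low-CO2 ones. Over all peaks, the share of signal above background kept at low CO2 was 0.656, 0.622, 0.586, 0.559 and 0.532 from the fifth of peaks with the lowest high-CO2 level to the highest, a fall of 0.125 (95% interval 0.0765 to 0.162, resampling chromosomes). One dilution would give the same share at every level, but the share rests on the assumed background, and the slope of low on high level, which does not, was 0.547 at the lower end and 0.506 at the upper end of the levels (difference 0.0408, interval -0.0366 to 0.132). Whether a weaker enrichment in the low-CO2 libraries or a loss of Kbu in the cells lowered these peaks cannot be told apart, because both would lower most peaks of the same 2 libraries.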
